A study of Mus musculus with 20 samples.

How the data were processed

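Bulk RNA-seq of sorted mouse cells was measured in 20 libraries. Per the labels' protocols, total RNA was extracted from sorted cells with MagZol reagent and the libraries were made by either of 2 sequencing providers; the labels do not say which library went where. The submitters' processing notes name Trim Galore 0.4.4, Bowtie2, Subread, featureCounts, RSEM, DESeq2 and the mm10 genome build, without stating the role or order of any of them. The values of the RFP and Bcl6 experiments were deposited as FPKM made by the authors, fragments or reads scaled to gene length and depth. The values of the Prdm1 and Tcf7 experiments were also deposited under the name FPKM, but they hold a gene signal without a gene length: reads divided by 1 size factor per library. All of the values in those 2 tables were whole multiples of the smallest value of their library (100% of values, tolerance 0.01 of a read). In the FPKM tables, the product of value and gene length was a whole multiple of 1 read for 97.1 to 97.9% of the low values checked (tolerance 0.02).

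Because of this unit mismatch, the thresholds written for FPKM were replaced in the Prdm1 and Tcf7 tables by thresholds on the signal scale, and the planned test on log2 values was kept. Values were used on the log2(value+1) scale, and every fold change is on that scale, so a pseudocount of 1 acts on FPKM in 2 experiments and on signal in the other 2. Genes entered a test with a value of at least 1 FPKM, or 50 in signal, in as many libraries as the smaller group has. The number of genes tested was 9717 of 12975 in the RFP experiment, 9573 of 13766 in the Bcl6 experiment, 10969 of 13624 in the Prdm1 experiment and 15210 of 25036 in the Tcf7 experiment. Gene symbols were matched to GENCODE vM21 (GRCm38, the assembly also called mm10) for coordinates, with 98.8% of the RFP table's symbols, 98.8% of the Bcl6 table's, 98.6% of the Prdm1 table's and 84.8% of the Tcf7 table's found.

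Groups were taken from the labels: RFP+CD160+ against RFP−CD160− cells (3 libraries each), and Cd8cre deletion of Bcl6, Prdm1 or Tcf7 against floxed littermates (2 libraries each). The labels name Cd8cre in every knockout genotype and in no littermate genotype. Within each comparison, an effect of Cd8cre itself therefore cannot be told apart from the loss of the gene. Each experiment was fitted alone in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend), without covariates, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All adjusted p-values for single genes come from limma, and all tests were two-sided. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of that comparison, for lists with at least 5 measured members. Camera with an estimated correlation and fry, which tests whether a list's genes moved on balance 1 way, were the alternatives. The 25 lists covered stem-like and memory, cytotoxic effector, NK receptor, residency and gut homing, inhibitory receptor and TCR-induced, cytokine and chemokine receptor, T-cell transcription factor, TCR signalling, cell cycle, oxidative phosphorylation, glycolysis, cholesterol synthesis, interferon-stimulated, survival and apoptosis, immediate-early and heat-shock, ribosomal protein, mitochondrially encoded genes, 7 lists of genes of other cells (epithelium, B and plasma cells, myeloid cells, gamma-delta T cells, CD4 and CD8αβ T cells, innate lymphoid and mast cells, and stroma with endothelium and erythroid cells) and sex-linked genes. The gamma-delta T cell list had no member that passed the filter of the limma fit in any experiment, and the mitochondrially encoded list had none in the Prdm1 and Tcf7 tables. Genes used for the sort (Bcl6 and Cd160) or deleted (Bcl6, Prdm1 and Tcf7) are counted where they belong to a list but are no independent finding.

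Up to 200 genes per direction with the smallest p in the RFP comparison, without Bcl6, Prdm1, Tcf7 and Cd160, were tested as 2 sets in each knockout with camera. Fold changes were correlated across genes for the 6 pairs of experiments over genes with a mean of at least 1 FPKM or 50 in signal, with an exact permutation of the group labels in both experiments. Genes are not independent replicates, so the p comes from the permuted libraries. The Prdm1 effect minus the Bcl6 effect was tested with limma over the 8 libraries of both experiments. The comparisons of knockouts share no libraries. Overlaps of called genes are given beside the number that independent lists would share.

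Genes named in the text follow a rule: 7 fixed genes (Bcl6, Prdm1, Tcf7, Cd160, Gzma, Gzmb and Cd8a), the 5 genes with the largest positive and the 5 with the largest negative log2 fold change among called genes at a mean of at least 5 FPKM or 250 in signal whose groups do not overlap, and up to 3 called members of each list by smallest p. Gene models, receptor segments, pseudogenes and sex-linked genes were left out of the ranking. The largest increases and decreases named below are the largest among the genes so ranked. The rule, the lists, the tests and the alternatives below, except those named as later additions, were chosen before the data were examined. The alternatives were pseudocounts of 0.1 and 0.5, no filter and a stricter filter on low values (5 FPKM or 250 in signal), rescaled library totals, quantile normalization, centring on the median of genes with a mean of at least 10 FPKM or 500 in signal, no trend, the replicate number as a replicate block, 1 fit over all 18 assigned libraries, a fold change of at least 2, and leaving out each library in turn. For the signature, set sizes of all called genes and of at most 50 genes were also tried. Later additions were edgeR 4.0.16 (quasi-likelihood, TMM) on the reads recovered for the Prdm1 experiment, and fits without epithelial, immediate-early or heat-shock genes. No such read test was run for the Tcf7 experiment, since the rule used here to accept recovered reads leaves out a step as near to 1 as that of 1 of its libraries (0.995), although the values themselves show the division.

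The total number of reads per library, from the value of 1 read, was 14.5 to 48.2 (in units of 1000000 reads). The spread between replicates exceeded counting error in every group, with a chi-square per degree of freedom of 4.23 to 69.1 over genes with at least 20 reads in a pair of libraries. The tests were run on simulated data with counts drawn from the means and depths of each experiment and 200 genes changed. Of genes changed 2-fold, 100 of 100 were called in the RFP simulation (9550 genes), 100 of 100 in the Bcl6 simulation (9428 genes), 98 of 99 in the Prdm1 simulation (10961 genes) and 99 of 100 in the Tcf7 simulation (15073 genes), and all 100 changed 4-fold were called in each. Unchanged genes called numbered 27, 12, 11 and 15 in the same order. For the difference of the Prdm1 and Bcl6 effects, 180 of 180 planted genes were called among 9210, with 18 others. The simulation used 1 dispersion per experiment for all genes and is optimistic where single genes vary more.

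The 2 libraries without a group were left out of every comparison and are described only as values. The labels do not state that replicates came from separate mice; where they did not, the p-values measure only the spread between samples. Gene symbols stand for whole genes, the labels do not describe how reads shared between near-identical copies were counted, and values of the alpha-defensins, of Hspa1a with Hspa1b and of the Klra receptors are therefore uncertain for single members.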

Results

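TCRαβ+CD8αα+ intraepithelial lymphocytes (IELs), T cells lodged between the epithelial cells of the mouse small intestine, were profiled by bulk RNA-seq in 4 comparisons. From Bcl6-RFP reporter mice, cells positive for RFP and CD160 gave 3 libraries (RFP+) and cells negative for both gave 3 (RFP−). The whole CD8αα+ population of mice that lost Bcl6, Prdm1 or Tcf7 through Cd8cre gave 2 libraries per knockout, each set against 2 libraries of floxed littermates. BCL6, BLIMP1 (encoded by Prdm1) and TCF1 (encoded by Tcf7) are transcription factors, and the comparisons ask which genes part RFP+ from RFP− IELs and how each factor's loss moves those genes. Depth, in units of 1000000 reads, was 14.5 to 16.9 in RFP+ libraries and 16.5 to 17.4 in RFP− libraries. It was 22.1 to 23 in the Bcl6 experiment, 30.1 to 38.4 in the Prdm1 experiment and 41 to 48.2 in the Tcf7 experiment. Another 2 libraries, which the labels put in no group, had 22.5 and 30.03. Values are FPKM in the RFP and Bcl6 experiments and size-factor-scaled reads (signal) in the Prdm1 and Tcf7 experiments, so levels are comparable only within an experiment.

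The deleted and sorted genes were read first in every library. Prdm1 (chromosome 10, 44437177 to 44528501 on GRCm38) stood at 639.9 and 362 in Prdm1 knockout libraries and 6092 and 5117 in their littermates. Tcf7 (chromosome 11, 52252371 to 52283014) stood at 7757 and 7993 in Tcf7 knockout libraries and 15430.3 and 15606 in littermates. Bcl6 (chromosome 16, 23965052 to 23988852) stood at 0.55 and 0.638 FPKM in Bcl6 knockout libraries and 0.772 and 0.735 FPKM in littermates, below the filter of 1 FPKM, so it was not tested and checks those labels only weakly. Whole-gene values include any exons that a floxed allele leaves in place. In the sorted cells Bcl6 was at 13.7, 14.2 and 18 FPKM in RFP+ libraries and 3.44, 3.3 and 3.59 FPKM in RFP− libraries. Cd160 (chromosome 3, 96798763 to 96829351) was at 242, 240.3 and 231 FPKM in RFP+ and 69.8, 61.9 and 66.3 FPKM in RFP− libraries.

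**Figure D1:**
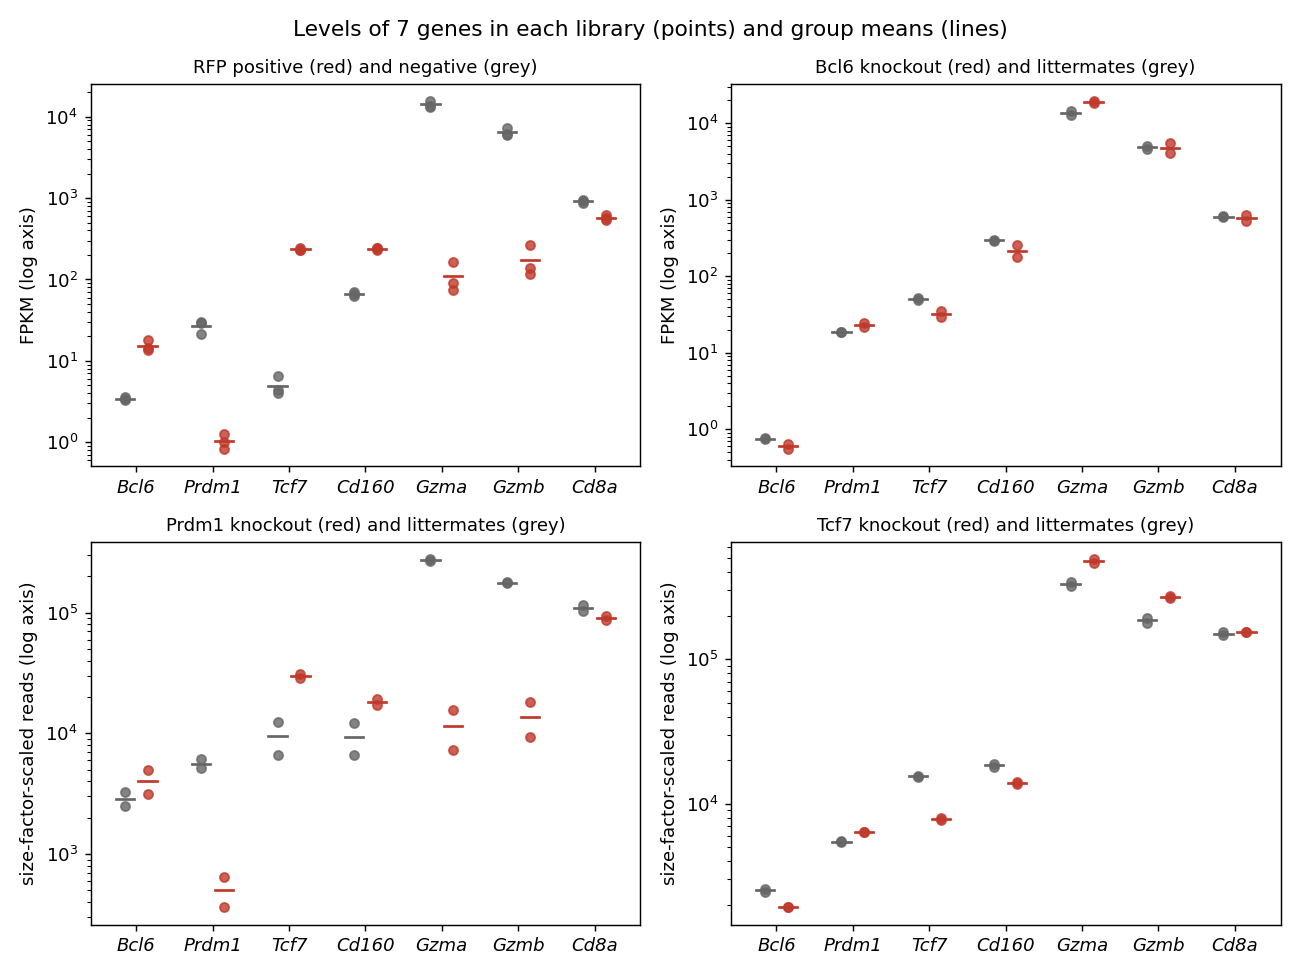
Levels of 7 genes fixed in advance in each library (points; log axis; FPKM in the RFP and Bcl6 panels, size-factor-scaled reads in the Prdm1 and Tcf7 panels), with a line at each group mean; red marks RFP+ or knockout libraries and grey marks RFP− or littermate libraries. Gzma averaged 110.1 ± 49.2 against 14130.0 ± 1273 FPKM (SD) in RFP+ against RFP− cells and 11457 ± 6002 against 272307 ± 7298 in Prdm1 knockout cells against littermates.

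RFP+ cells were rich in transcripts of stem-like T cells and RFP− cells in those of cytotoxic effectors. Tcf7 encodes the TCF1 factor of naive and memory T cells and averaged 234 ± 10.1 against 4.93 ± 1.33 FPKM in RFP+ against RFP− cells (SD, n = 3 per group). Its log2 fold change was 5.33 ± 0.14 (SE, limma adjusted p = 6.0e-07). Id3, an inhibitor of E proteins (chromosome 4, 136143497 to 136145755), averaged 27.2 ± 4.35 against 1.24 ± 0.293 FPKM (log2 fold change 3.65, adjusted p = 1.2e-06). The granzyme gene Gzma (chromosome 13, 113093825 to 113100981) averaged 110.1 ± 49.2 against 14130.0 ± 1273 FPKM (log2 fold change -7.07, adjusted p = 1.3e-06). Gzmb (chromosome 14, 56258838 to 56262260) averaged 173 ± 81.8 against 6499 ± 704 FPKM (log2 fold change -5.31, adjusted p = 4.8e-06). Prdm1 averaged 1.04 ± 0.223 against 26.9 ± 4.76 (log2 fold change -3.76, adjusted p = 1.2e-06), lower in RFP+ cells. Cd8a averaged 574 ± 35.5 against 913 ± 38 (log2 fold change -0.67, adjusted p = 2.1e-04).

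The other largest increases were Batf3 (15.1 ± 1.56 against 0.539 ± 0.347) and Tgm2 (28.1 ± 2.69 against 0.662 ± 0.271) and the cytokine gene Csf2 (13.5 ± 5.45 against 0.492 ± 0.23). Beside both granzymes, Gpx8 (0.158 ± 0.144 against 37.8 ± 11.6) and Tmem273 (1.33 ± 0.517 against 54.8 ± 3.59) and the osteopontin gene Spp1 (0.46 ± 0.113 against 22.8 ± 0.914) fell most. Il2rb, a shared chain of the IL-2 and IL-15 receptors, fell from 851 ± 50.6 to 255 ± 30.01 FPKM. The TCR-induced gene Tnfrsf9 (12.1 ± 2.26 against 72.2 ± 0.964), the homing receptor gene Cxcr6 (24.5 ± 1.72 against 99.5 ± 5.36) and Runx2 (1.01 ± 0.131 against 10.2 ± 0.366) were lower in RFP+ cells as well. Among NK receptor genes, the adaptor gene Tyrobp (194 ± 24 against 784 ± 60.2) fell and Klrk1, the NKG2D gene (4.9 ± 0.174 against 0.287 ± 0.0673), rose. Nr4a1 (62.8 ± 5.22 against 26.5 ± 1.51), Cd2 (22.2 ± 1.97 against 2.2 ± 0.328) and Kit (64.1 ± 7.75 against 20.8 ± 3.28) were higher in RFP+ cells. The adjusted p of the genes in these comparisons in limma ran from 9.1e-08 to 6.2e-05.

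Of 25 fixed lists, 12 were called by camera in RFP+ cells, and 2 of these held with an estimated correlation. Stem-like and memory genes rose (14 higher of 19, 15 higher adjusted over the list alone). The stem-like and memory median was 1.52 on the log2 scale (adjusted p = 6.2e-09, adjusted p = 0.035 with an estimated correlation). Cytotoxic effector genes fell (1 higher and 21 lower of 24, 1 higher and 22 lower adjusted over the list alone). The cytotoxic effector median was -1.28 on the log2 scale (adjusted p = 4.6e-10, adjusted p = 0.035 with an estimated correlation). Immediate-early and heat-shock genes rose (29 higher and 2 lower of 34, 30 higher and 2 lower adjusted over the list alone). The immediate-early and heat-shock median was 0.75 on the log2 scale (adjusted p = 1.5e-10, adjusted p = 0.34 with an estimated correlation). Ribosomal protein genes rose (56 higher and 1 lower of 76, 60 higher and 1 lower adjusted over the list alone). The ribosomal protein median was 0.31 on the log2 scale (adjusted p = 5.4e-16, adjusted p = 0.46 with an estimated correlation). Cell cycle genes, Mki67 among them, fell (24 lower of 38, 26 lower adjusted over the list alone). The cell cycle median was -0.54 on the log2 scale (adjusted p = 5.6e-06, adjusted p = 0.59 with an estimated correlation). Cholesterol synthesis genes, led by Mvd and Lss, fell (16 lower of 24, 18 lower adjusted over the list alone). The cholesterol synthesis median was -0.35 on the log2 scale (adjusted p = 1.7e-06, adjusted p = 0.44 with an estimated correlation). NK receptor genes rose on balance (14 higher and 6 lower of 26, the same adjusted over the list alone). The NK receptor median was 0.71 on the log2 scale (adjusted p = 0.022, adjusted p = 0.46 with an estimated correlation). Interferon-stimulated genes rose (13 higher and 2 lower of 36, the same adjusted over the list alone). The interferon-stimulated median was 0.10 on the log2 scale (adjusted p = 0.0016, adjusted p = 0.46 with an estimated correlation). Survival and apoptosis genes fell on balance (3 higher and 13 lower of 32, 4 higher and 15 lower adjusted over the list alone). The survival and apoptosis median was -0.21 on the log2 scale (adjusted p = 0.022, adjusted p = 0.28 with an estimated correlation). Mitochondrially encoded genes rose (6 higher of 12, the same adjusted over the list alone). The mitochondrially encoded median was 0.30 on the log2 scale (adjusted p = 0.0010, adjusted p = 0.46 with an estimated correlation). Cytokine and chemokine receptor genes rose on balance (11 higher and 6 lower of 25, 13 higher and 6 lower adjusted over the list alone). The cytokine and chemokine receptor median was 0.19 on the log2 scale (adjusted p = 0.045, adjusted p = 0.46 with an estimated correlation). Oxidative phosphorylation genes fell (2 higher and 16 lower of 59, 2 higher and 14 lower adjusted over the list alone). The oxidative phosphorylation median was -0.11 on the log2 scale (adjusted p = 0.031, adjusted p = 0.65 with an estimated correlation). That last direction turned with library totals rescaled (12 higher and 3 lower). The same rescaling gave 22 higher and 1 lower interferon-stimulated, 73 higher ribosomal protein and 11 higher mitochondrially encoded genes, and 5 higher and 9 lower survival and apoptosis genes.

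Lists that did not pass in camera held calls in both directions. Residency and gut homing genes had 11 higher and 9 lower of 26, 12 higher and 10 lower adjusted over the list alone (adjusted p = 0.59). Inhibitory receptor and TCR-induced genes had 7 higher and 9 lower of 24, 9 higher and 11 lower adjusted over the list alone (adjusted p = 0.59). T-cell transcription factor genes had 20 higher and 14 lower of 52, 22 higher and 20 lower adjusted over the list alone (adjusted p = 0.19). TCR signalling genes had 10 higher and 9 lower of 28, the same adjusted over the list alone (adjusted p = 0.40). Glycolysis genes had 7 higher and 5 lower of 22, 8 higher and 5 lower adjusted over the list alone (adjusted p = 0.39). Epithelial genes had 1 higher and 2 lower of 21, 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.087). Myeloid cell genes had 1 higher and 4 lower of 8, the same adjusted over the list alone (adjusted p = 0.11). CD4 and CD8αβ T cell genes had 3 higher and 1 lower of 6, 3 higher and 2 lower adjusted over the list alone (adjusted p = 0.40). With fewer than 5 measured genes, the next lists were only counted. B and plasma cell genes had 1 lower of 1, the same adjusted over the list alone. Innate lymphoid and mast cell genes had 1 higher and 3 lower of 4, the same adjusted over the list alone. Stroma, endothelium and erythroid genes had 1 lower of 3, the same adjusted over the list alone. Sex-linked genes had 1 higher of 4, no call adjusted over the list alone. The residency list had a median of -0.05 but a mean of 0.07. With library totals rescaled, TCR signalling genes had 16 higher and 6 lower and T-cell transcription factor genes other than Bcl6 25 and 7, against 19 and 14 before. The residency median changed sign under at least 1 rescaling, like those of the inhibitory receptor, oxidative phosphorylation and stroma lists.

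In all, limma called 1591 genes higher and 2098 lower in RFP+ cells among 9717 tested, 193 and 244 of them by at least 2-fold. Gzma and Gzmb together took up 7.32 to 8.27% of all FPKM in RFP− libraries and 0.0793 to 0.18% in RFP+ libraries, so the split depends on the scale. It was 3290 higher and 1173 lower with library totals rescaled, which moved the median gene by 0.16 on the log2 scale, 2024 and 1744 with quantile normalization, and 2200 and 1595 when centred on well expressed genes.

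**Figure D2:**
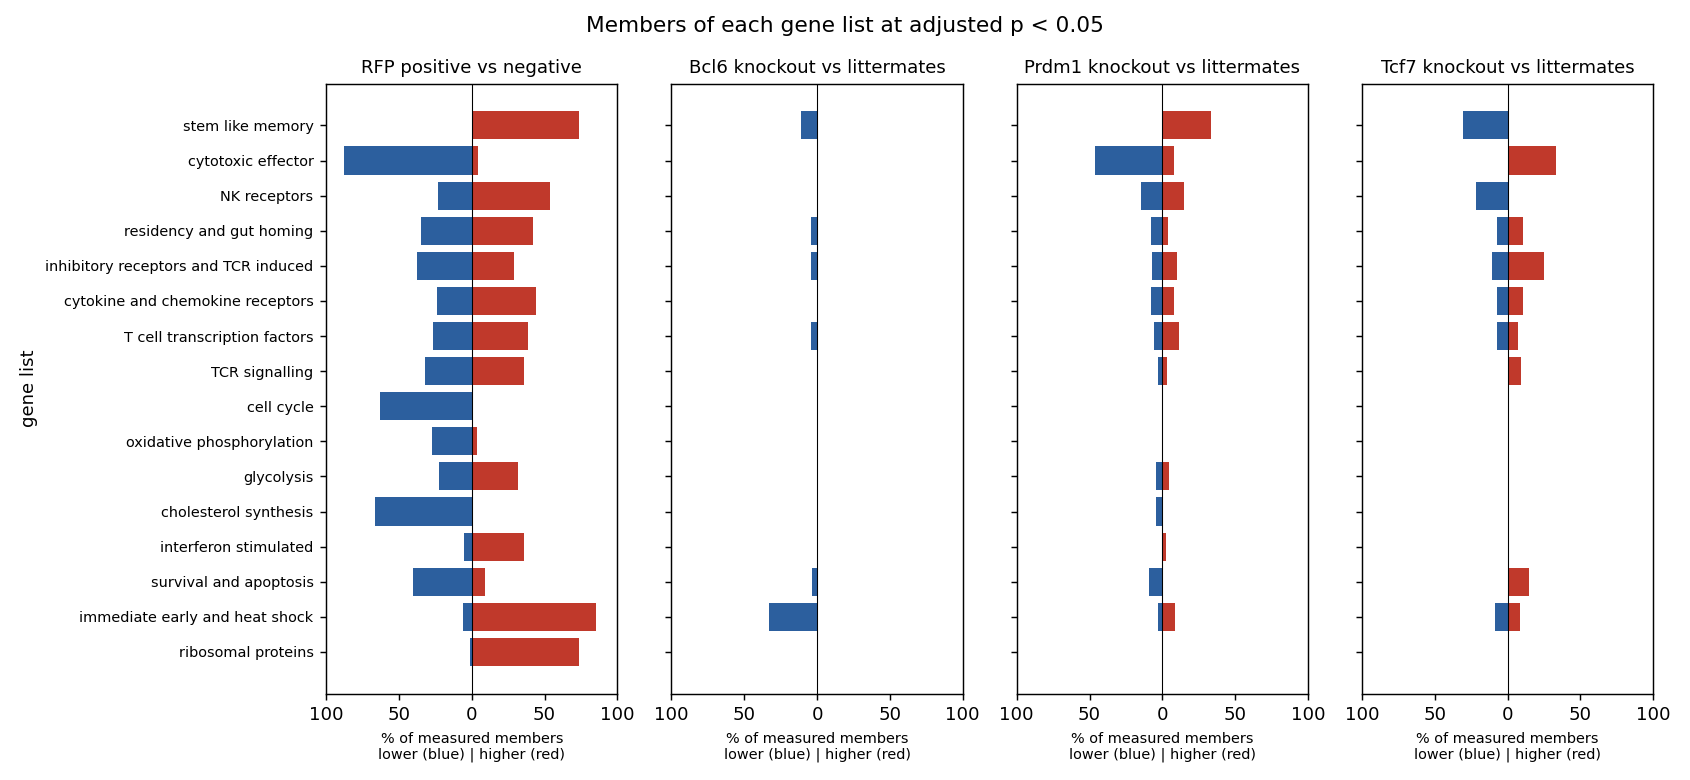
Share of the measured members of 16 fixed gene lists called higher (red, right) or lower (blue, left) at an adjusted p under 0.05 in each of the 4 comparisons; the x axis is in percent of measured members. In RFP+ cells 14 of 19 stem-like and memory genes were higher and 21 of 24 cytotoxic effector genes lower; in Prdm1 knockout cells 7 of 21 and 12 of 26 went the same way. In the RFP panel, the direction of the residency, inhibitory receptor and oxidative phosphorylation medians flips under at least 1 rescaling.

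The Bcl6 knockout asks what IELs lose without BCL6. The heat-shock gene Hspa1b had the largest decrease. It averaged 10.6 ± 3.03 against 97.4 ± 1.66 FPKM in knockout against littermate libraries (SD, n = 2 per group, log2 fold change -3.11, limma adjusted p = 5.3e-04). Hspa1a averaged 117 ± 15.3 against 654 ± 53.2 (log2 fold change -2.47, adjusted p = 5.8e-04). The small heat-shock gene Hspb1 (5.84 ± 1.61 against 36.1 ± 2.35) fell with them (adjusted p = 0.0012). Among stem-like genes, Id3 fell from 46.9 ± 1.14 to 13.2 ± 3.35 FPKM (log2 fold change -1.77, adjusted p = 0.0054). The lymphotoxin gene Ltb (69.6 ± 0.157 against 142 ± 14.5) and the transcription factor gene Hopx (1.11 ± 0.242 against 6.004 ± 0.785) also fell (adjusted p = 0.042 and 0.0068). So did Nr4a1 (87.6 ± 12.2 against 221 ± 17.8) and Cdkn1a (4.53 ± 0.338 against 15.2 ± 2.95), with an adjusted p of 0.014 and 0.011. Irak3, a brake on Toll-like receptor signalling, rose (8.88 ± 0.775 against 1.58 ± 0.239, log2 fold change 1.94, adjusted p = 0.0030). The Paneth cell genes Defa39 (3.78 ± 0.516 against 33.4 ± 3.29), Defa30 (7.55 ± 0.0371 against 39.6 ± 0.0914) and Defa24 (31 ± 3.43 against 119 ± 5.91) fell (adjusted p from 5.3e-04 to 0.0015). These alpha-defensins are near-identical copies whose single values are uncertain. Defa24 also ran from 19.5 to 141 FPKM among the RFP− libraries, which share 1 sort. The spread of 2 libraries per group may therefore understate how much these transcripts vary, and whether their fall comes from BCL6 loss was not tested. The colipase gene Clps (0.435 ± 0.514 against 6.93 ± 3.06) fell too (adjusted p = 0.014).

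The other fixed genes did not pass in the Bcl6 knockout. Tcf7 averaged 32.1 ± 3.91 against 50.4 ± 1.8 (log2 fold change -0.64, adjusted p = 0.30). Cd160 averaged 217 ± 52.4 against 295 ± 7.92 (log2 fold change -0.46, adjusted p = 0.85). Prdm1 averaged 23.3 ± 1.77 against 18.5 ± 0.02004 (log2 fold change 0.31, adjusted p = 0.92). Gzma averaged 18932 ± 919 against 13803 ± 1234 (log2 fold change 0.46, adjusted p = 0.91). Gzmb averaged 4774 ± 969 against 4832 ± 222 (log2 fold change -0.03, adjusted p = 0.99). Cd8a averaged 582 ± 71.8 against 600.5 ± 10.1 (log2 fold change -0.05, adjusted p = 0.98). Tcf7 passed only with a knockout library left out, where a single library is assumed to vary like the others. Its adjusted p was then 0.0086 without Bcl6 knockout replicate 1 and 1.0e-04 without replicate 2. With a knockout library left out, calls were also gained for Cd160 without replicate 1 (adjusted p = 2.3e-05) and Gzma without replicate 1 (adjusted p = 0.019).

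Of the lists in the Bcl6 knockout, 12 were called by camera. With an estimated correlation no call held, and the smallest adjusted p among the 12 was 0.26. Immediate-early and heat-shock genes fell (11 lower of 33, 21 lower adjusted over the list alone). The immediate-early and heat-shock median was -0.65 on the log2 scale (adjusted p = 1.8e-37, adjusted p = 0.26 with an estimated correlation). This was the only list of the 12 that passed in fry (adjusted p = 0.036). Stem-like and memory genes, Id3 and Ltb among them, fell (2 lower of 18, 6 lower adjusted over the list alone). The stem-like and memory median was -0.34 on the log2 scale (adjusted p = 2.9e-07, adjusted p = 0.27 with an estimated correlation). Inhibitory receptor and TCR-induced genes fell (1 lower of 24, 6 lower adjusted over the list alone). The inhibitory receptor and TCR-induced median was -0.15 on the log2 scale (adjusted p = 1.1e-04, adjusted p = 0.36 with an estimated correlation). T-cell transcription factor genes fell (2 lower of 48, 6 lower adjusted over the list alone). The T-cell transcription factor median was -0.11 on the log2 scale (adjusted p = 2.1e-04, adjusted p = 0.27 with an estimated correlation). Residency and gut homing genes fell (1 lower of 25, the same adjusted over the list alone). The residency and gut homing median was -0.10 on the log2 scale (adjusted p = 0.013, adjusted p = 0.40 with an estimated correlation). The remaining lists moved in camera with no single gene called by limma. Glycolysis genes fell (no call of 23, 1 lower adjusted over the list alone). The glycolysis median was -0.20 on the log2 scale (adjusted p = 4.5e-05, adjusted p = 0.44 with an estimated correlation). Cytokine and chemokine receptor genes fell (no call of 25, the same adjusted over the list alone). The cytokine and chemokine receptor median was -0.15 on the log2 scale (adjusted p = 0.0010, adjusted p = 0.43 with an estimated correlation). Ribosomal protein genes fell (no call of 77, the same adjusted over the list alone). The ribosomal protein median was -0.08 on the log2 scale (adjusted p = 0.023, adjusted p = 0.72 with an estimated correlation). CD4 and CD8αβ T cell genes fell (no call of 10, 1 higher and 4 lower adjusted over the list alone). The CD4 and CD8αβ T cell median was -0.30 on the log2 scale (adjusted p = 0.013, adjusted p = 0.37 with an estimated correlation). Cell cycle genes rose (no call of 42, the same adjusted over the list alone). The cell cycle median was 0.18 on the log2 scale (adjusted p = 0.0026, adjusted p = 0.36 with an estimated correlation). Oxidative phosphorylation genes rose (no call of 59, the same adjusted over the list alone). The oxidative phosphorylation median was 0.13 on the log2 scale (adjusted p = 8.2e-04, adjusted p = 0.47 with an estimated correlation). Myeloid cell genes rose (no call of 14, the same adjusted over the list alone). The myeloid cell median was 0.57 on the log2 scale (adjusted p = 0.0010, adjusted p = 0.44 with an estimated correlation).

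The other lists did not pass in camera. Epithelial genes had 4 lower of 39, 3 higher and 7 lower adjusted over the list alone (adjusted p = 0.17). Survival and apoptosis genes had 1 lower of 30, 4 lower adjusted over the list alone (adjusted p = 0.086). Cytotoxic effector genes had no call of 26, 2 lower adjusted over the list alone (adjusted p = 0.45). NK receptor genes had no call of 23, the same adjusted over the list alone (adjusted p = 0.95). TCR signalling genes had no call of 30, the same adjusted over the list alone (adjusted p = 0.39). Cholesterol synthesis genes had no call of 24, the same adjusted over the list alone (adjusted p = 0.086). Interferon-stimulated genes had no call of 36, the same adjusted over the list alone (adjusted p = 0.45). Mitochondrially encoded genes had no call of 13, the same adjusted over the list alone (adjusted p = 0.19). Stroma, endothelium and erythroid genes had no call of 5, the same adjusted over the list alone (adjusted p = 0.34). B and plasma cell genes had no call of 4, 1 lower adjusted over the list alone. Innate lymphoid and mast cell genes had no call of 3, the same adjusted over the list alone. Sex-linked genes had no call of 4, the same adjusted over the list alone. In the 17 lists where limma called no gene, 38 of 418 members had an unadjusted p under 0.05. Among all 9573 tested genes, 559 did. Median and mean differed in sign for the NK receptor, TCR signalling, survival, B and plasma, innate lymphoid and stroma lists. Medians of the TCR signalling, survival and epithelium lists changed sign under at least 1 rescaling.

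The Bcl6 comparison called 3 genes higher and 37 lower among 9573 (limma, 559 with an unadjusted p under 0.05). Single libraries weigh heavily at n = 2: without Bcl6 knockout replicate 1 the counts were 730 and 832, without knockout replicate 2 68 and 131, and without littermate replicate 2 the higher count was 14. The lone library left in a group is then assumed to vary like the others.

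Granzyme transcripts were much lower in the Prdm1 knockout, in bulk libraries of the whole CD8αα+ population. Such values cannot part a change within cells from a change in the mix of cells. Gzma averaged 11457 ± 6002 against 272307 ± 7298 in knockout against littermate libraries (signal ± SD, n = 2 per group, log2 fold change -4.68, limma adjusted p = 0.0025). Gzmb averaged 13729 ± 6250.4 against 177166 ± 1966 (log2 fold change -3.77, adjusted p = 0.0027). The granzyme gene Gzmk (43.8 ± 35.5 against 1025 ± 105) and the chemokine gene Ccl5 (24477 ± 2413 against 121326 ± 9641) fell too (adjusted p = 0.0059 and 0.0025). Tcf7 rose (30025 ± 1514 against 9536 ± 4145, log2 fold change 1.73, adjusted p = 0.016). The receptor genes Kit (37380.2 ± 595 against 14725 ± 4429) and Slamf6 (522 ± 24.9 against 234 ± 33.9) and the transcription factor gene Nfkb1 (17804 ± 1109 against 8422 ± 1644) rose with it (adjusted p from 0.011 to 0.014). Batf3, higher in RFP+ cells, rose (1415 ± 264 against 209.8 ± 177, adjusted p = 0.026). Gpx8, lower in RFP+ cells, fell (41.7 ± 44.3 against 1051 ± 548, adjusted p = 0.017). Prdm1 averaged 501 ± 197 against 5604 ± 689.7 (log2 fold change -3.53, adjusted p = 0.0025), the deleted gene and no independent finding.

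Beside Gzmk and Gpx8, the largest decreases were Lyl1 (9.45 ± 1.61 against 459 ± 105), Ky (34.3 ± 26.4 against 1017 ± 402) and Il34 (8.4 ± 0.113 against 255 ± 11.3). Shank1 (255 ± 53.7 against 31.6 ± 21.2) and Kcnk1 (1403 ± 212 against 174 ± 79.5) had the largest increases, with Ccn1 (261 ± 4.64 against 36.1 ± 10.02) and Ceacam1 (515 ± 96.2 against 76.1 ± 2.24). The integrin gene Itgam (58.9 ± 26 against 644 ± 105), Il2rb (51056 ± 4957 against 101220.2 ± 2818) and Cxcr6 (1866 ± 286 against 5452 ± 103) fell. Tnf rose (140.0 ± 15.2 against 23.8 ± 10.3). The limma adjusted p of the genes in these comparisons ran from 0.0022 to 0.020. Cd160, Bcl6 and Cd8a did not pass in the fit without a replicate term. Cd160 averaged 18261 ± 1345 against 9411 ± 4039.5 (log2 fold change 1.02, adjusted p = 0.079). Bcl6 averaged 4041 ± 1294 against 2875 ± 541 (log2 fold change 0.47, adjusted p = 0.31). Cd8a averaged 89746 ± 4894 against 110409 ± 9186 (log2 fold change -0.30, adjusted p = 0.42). With the replicate number as a block, which parts the sexes, Cd160 (adjusted p = 8.2e-05) and Bcl6 (adjusted p = 0.0017) passed with the same fold changes, and Cd8a (adjusted p = 0.073) did not.

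Of the lists in the Prdm1 knockout, 7 were called by camera. None of the 7 held with an estimated correlation or in fry. Both of these, like the counts below, rest on the fit without a replicate term. The replicate number parts the sexes here, so the difference between the sexes stays in the spread of that fit. Stem-like and memory genes rose (7 higher of 21, 11 higher adjusted over the list alone). The stem-like and memory median was 0.74 on the log2 scale (adjusted p = 1.2e-07, adjusted p = 0.62 with an estimated correlation). Cytotoxic effector genes fell (2 higher and 12 lower of 26, 2 higher and 15 lower adjusted over the list alone). The cytotoxic effector median was -0.67 on the log2 scale (adjusted p = 1.6e-07, adjusted p = 0.49 with an estimated correlation). Epithelial genes rose (25 higher of 41, 34 higher adjusted over the list alone). The epithelium median was 1.74 on the log2 scale (adjusted p = 9.8e-27, adjusted p = 0.49 with an estimated correlation). Muc13 (1239 ± 112 against 258 ± 49.6) and Krt8 (1012 ± 117 against 224 ± 36.7) led the epithelial list, which had 17 higher with quantile normalization. Immediate-early and heat-shock genes rose on balance (3 higher and 1 lower of 34, 13 higher and 1 lower adjusted over the list alone). The immediate-early and heat-shock median was 0.35 on the log2 scale (adjusted p = 1.3e-06, adjusted p = 0.90 with an estimated correlation). Their higher count was 9 with library totals rescaled, 7 when centred on well expressed genes and 6 with quantile normalization. Ribosomal protein genes rose in camera alone (no call of 77, the same adjusted over the list alone). The ribosomal protein median was 0.26 on the log2 scale (adjusted p = 1.6e-07, adjusted p = 0.96 with an estimated correlation). Neither limma nor edgeR called a ribosomal protein gene. Survival and apoptosis genes fell (3 lower of 33, the same adjusted over the list alone). The survival and apoptosis median was -0.21 on the log2 scale (adjusted p = 0.0043, adjusted p = 0.84 with an estimated correlation). Cholesterol synthesis genes fell (1 lower of 24, the same adjusted over the list alone). The cholesterol synthesis median was -0.23 on the log2 scale (adjusted p = 0.016, adjusted p = 0.96 with an estimated correlation).

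The other lists did not pass after Prdm1 loss. NK receptor genes had 4 higher and 4 lower of 27, 5 higher and 5 lower adjusted over the list alone (adjusted p = 0.93). Residency and gut homing genes had 1 higher and 2 lower of 25, 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.57). Inhibitory receptor and TCR-induced genes had 3 higher and 2 lower of 29, 6 higher and 5 lower adjusted over the list alone (adjusted p = 0.74). Cytokine and chemokine receptor genes had 2 higher and 2 lower of 26, 4 higher and 3 lower adjusted over the list alone (adjusted p = 0.45). T-cell transcription factor genes had 6 higher and 3 lower of 54, 9 higher and 4 lower adjusted over the list alone (adjusted p = 0.27). TCR signalling genes had 1 higher and 1 lower of 32, the same adjusted over the list alone (adjusted p = 0.74). Glycolysis genes had 1 higher and 1 lower of 22, 1 higher and 2 lower adjusted over the list alone (adjusted p = 0.22). Interferon-stimulated genes had 1 higher of 37, the same adjusted over the list alone (adjusted p = 0.74). Cell cycle genes had no call of 44, the same adjusted over the list alone (adjusted p = 0.49). Oxidative phosphorylation genes had no call of 57, the same adjusted over the list alone (adjusted p = 0.74). Myeloid cell genes had 2 higher and 3 lower of 12, 6 higher and 3 lower adjusted over the list alone (adjusted p = 0.29). CD4 and CD8αβ T cell genes had no call of 10, the same adjusted over the list alone (adjusted p = 0.84). Stroma, endothelium and erythroid genes had no call of 9, the same adjusted over the list alone (adjusted p = 0.17). B and plasma cell genes had no call of 3, the same adjusted over the list alone. Innate lymphoid and mast cell genes had 1 higher of 4, 2 higher adjusted over the list alone. Sex-linked genes had no call of 4, the same adjusted over the list alone. In the 7 lists where limma called no gene, 13 of 204 members had an unadjusted p under 0.05. Among all 10969 tested genes, 2260 did, a larger share. edgeR called 1 gene in each of the B and plasma cell and the CD4 and CD8αβ T cell lists and none in the other 5. Median and mean differed in sign for the NK receptor, TCR signalling and interferon-stimulated lists. Medians of the NK receptor, residency, TCR signalling, cell cycle, oxidative phosphorylation, interferon-stimulated and B and plasma cell lists changed sign under at least 1 rescaling.

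The Prdm1 comparison called 471 genes higher and 279 lower among 10969, 375 and 121 of them by at least 2-fold. Of these calls, 185 higher and 263 lower genes were also tested in the RFP experiment, whose filter is on another scale. Most of the higher genes were thus below the filter, or not listed, in the sorted RFP+ and RFP− cells. Replicate 1 of both genotypes expressed the Y-linked gene Ddx3y (11544 in the knockout and 11359 in the littermate) and replicate 2 hardly did (131 and 119), so sex was balanced between genotypes. A fit with sex as a term, the same as the replicate block, called 1210 higher and 1176 lower. Without littermate replicate 2 the counts were 721 and 534.

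In the Tcf7 knockout 7 of 23 stem-like and memory genes, the deleted Tcf7 among them, were lower and 9 of 27 cytotoxic effector genes higher. Neither list passed in camera with an estimated correlation (adjusted p = 0.46 and 0.46) or in fry. Tcf7 itself averaged 7875 ± 167 against 15518 ± 124 in knockout against littermate libraries (signal ± SD, n = 2 per group, log2 fold change -0.98, limma adjusted p = 2.1e-07). Wnt11 fell most (60.3 ± 6.25 against 434 ± 23.8, log2 fold change -2.83, adjusted p = 1.1e-05). Lrrk2 (213 ± 4.1 against 870.4 ± 68.2) and Dkk3 (94.5 ± 8.33 against 309 ± 2.998) followed, with Kcnip2 (175 ± 45.3 against 546 ± 42.5) and Slamf6 (177 ± 35.6 against 467 ± 13.6) (adjusted p from 4.7e-06 to 4.8e-04). The receptor gene Kit (14596 ± 444 against 21885 ± 401) fell (adjusted p = 1.5e-05). Bcl6 averaged 1939 ± 15.2 against 2530.4 ± 83.3 (log2 fold change -0.38, adjusted p = 0.0065), lower in the knockout. Cd160 averaged 13959 ± 242 against 18498 ± 602 (log2 fold change -0.41, adjusted p = 2.6e-04), lower as well. Among genes that the naming rule ranks, Pdcd1, the PD-1 gene, rose most (876 ± 69.4 against 143 ± 3.47, log2 fold change 2.60, adjusted p = 1.0e-06). Some gene models that the rule leaves out rose more, as given below.

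Granzyme genes and Prdm1 rose in the Tcf7 knockout. Gzmb averaged 269828 ± 4767 against 185149 ± 9575 (log2 fold change 0.54, adjusted p = 5.6e-05). Gzma averaged 476506 ± 18710.0 against 332789 ± 15634 (log2 fold change 0.52, adjusted p = 1.4e-04). Prdm1 averaged 6370.4 ± 13.1 against 5487 ± 41 (log2 fold change 0.22, adjusted p = 0.045). Quantile normalization made both granzyme fold changes 0, so both calls were lost. That outcome is fixed for a gene of the same rank in every library, as Gzma was at the top of each Tcf7 library. Both granzyme calls were also lost without limma's trend and in 1 fit over all experiments. Of 43 called genes named by the rule, 39 lost their call in at least 1 alternative, most often in these last 2 fits. Thbs1 (266 ± 51.6 against 50.7 ± 27.9, adjusted p = 0.0011) was among the largest increases. So were the Paneth cell genes Defa22 (588 ± 71.6 against 179.9 ± 10.8), Defa33 (469.7 ± 5.62 against 148 ± 2.59) and Defa21 (632 ± 9.98 against 206 ± 44.2), with adjusted p from 4.8e-05 to 8.6e-05. The T-cell genes Cd6 (599.8 ± 11.6 against 312 ± 23.7), Ctla4 (1880.3 ± 2.16 against 1171 ± 97) and Cxcr6 (9729 ± 169 against 6313 ± 606) rose (adjusted p from 6.8e-05 to 0.0013). The NK receptor gene Klre1 (2573 ± 159 against 4092 ± 51.2) fell (adjusted p = 5.2e-05). Cd8a averaged 153569 ± 143 against 150220.4 ± 3715 (log2 fold change 0.03, adjusted p = 0.86) and did not pass.

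Of the lists in the Tcf7 knockout, 8 were called by camera. None of the 8 held with an estimated correlation or in fry. Stem-like and memory genes fell (7 lower of 23, 1 higher and 8 lower adjusted over the list alone). The stem-like and memory median was -0.15 on the log2 scale (adjusted p = 1.4e-05, adjusted p = 0.46 with an estimated correlation). Cytotoxic effector genes rose (9 higher of 27, 13 higher and 3 lower adjusted over the list alone). The cytotoxic effector median was 0.21 on the log2 scale (adjusted p = 1.3e-08, adjusted p = 0.46 with an estimated correlation). NK receptor genes fell on balance (6 lower of 28, 5 higher and 12 lower adjusted over the list alone). The NK receptor median was -0.25 on the log2 scale (adjusted p = 8.8e-04, adjusted p = 0.46 with an estimated correlation). Survival and apoptosis genes, Pim2 and Bmf among them, rose (5 higher of 34, 6 higher adjusted over the list alone). The survival and apoptosis median was 0.08 on the log2 scale (adjusted p = 3.3e-04, adjusted p = 0.46 with an estimated correlation). TCR signalling genes rose (3 higher of 33, 4 higher and 1 lower adjusted over the list alone). The TCR signalling median was 0.03 on the log2 scale (adjusted p = 0.036, adjusted p = 0.46 with an estimated correlation). Oxidative phosphorylation genes rose in camera alone (no call of 58, the same adjusted over the list alone). The oxidative phosphorylation median was 0.04 on the log2 scale (adjusted p = 0.038, adjusted p = 0.49 with an estimated correlation). Epithelial genes rose on balance (11 higher and 2 lower of 41, 22 higher and 3 lower adjusted over the list alone). The epithelium median was 0.33 on the log2 scale (adjusted p = 8.3e-12, adjusted p = 0.37 with an estimated correlation). CD4 and CD8αβ T cell genes rose (3 higher of 12, 6 higher and 1 lower adjusted over the list alone). The CD4 and CD8αβ T cell median was 0.36 on the log2 scale (adjusted p = 0.0022, adjusted p = 0.46 with an estimated correlation).

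The other lists did not pass after Tcf7 loss. Residency and gut homing genes had 3 higher and 2 lower of 28, 9 higher and 7 lower adjusted over the list alone (adjusted p = 0.31). Inhibitory receptor and TCR-induced genes had 7 higher and 3 lower of 28, 8 higher and 5 lower adjusted over the list alone (adjusted p = 0.12). Cytokine and chemokine receptor genes had 3 higher and 2 lower of 28, 6 higher and 5 lower adjusted over the list alone (adjusted p = 0.55). T-cell transcription factor genes had 4 higher and 4 lower of 55, 6 higher and 6 lower adjusted over the list alone (adjusted p = 0.75). Immediate-early and heat-shock genes had 3 higher and 3 lower of 34, 5 higher and 7 lower adjusted over the list alone (adjusted p = 0.58). Cell cycle genes had no call of 45, the same adjusted over the list alone (adjusted p = 0.079). Glycolysis genes had no call of 24, the same adjusted over the list alone (adjusted p = 0.78). Cholesterol synthesis genes had no call of 24, the same adjusted over the list alone (adjusted p = 0.97). Interferon-stimulated genes had no call of 42, the same adjusted over the list alone (adjusted p = 0.78). Ribosomal protein genes had no call of 82, the same adjusted over the list alone (adjusted p = 0.69). Myeloid cell genes had 2 higher of 11, the same adjusted over the list alone (adjusted p = 0.12). B and plasma cell genes had no call of 5, the same adjusted over the list alone (adjusted p = 0.12). Stroma, endothelium and erythroid genes had 2 higher of 9, 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.082). Innate lymphoid and mast cell genes had 1 lower of 4, the same adjusted over the list alone. Sex-linked genes had no call of 1, the same adjusted over the list alone. In the 8 lists where limma called no gene, 33 of 281 members had an unadjusted p under 0.05. Among all 15210 tested genes, 1909 did, a similar share. The inhibitory receptor, glycolysis and sex-linked medians changed sign under at least 1 rescaling, and the cholesterol synthesis median had the opposite sign to its test.

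The Tcf7 comparison called 226 genes higher and 187 lower among 15210, 35 and 35 of them by at least 2-fold. Without limma's mean-variance trend it called 6 and 3. Without littermate replicate 1 the counts were 370 and 357, without littermate replicate 2 399 and 339, without knockout replicate 1 123 and 120, and without knockout replicate 2 125 and 143.

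The genes that part RFP+ from RFP− cells were then followed as sets through each knockout. Each knockout library holds the whole CD8αα+ population. Whether a set moved within cells or through a changed mix of cells was therefore not tested. Prdm1 loss raised the set higher in RFP+ cells (197 of 198 genes positive, median log2 fold change 0.68, camera adjusted p = 7.2e-53, adjusted p = 0.065 with an estimated correlation). The opposite set fell (195 of 199 genes negative, median log2 fold change -0.83, camera adjusted p = 1.1e-59, adjusted p = 0.051 with an estimated correlation). Both estimated correlations come from the Prdm1 fit without a replicate term, in which the difference between the sexes stays in the spread. Bcl6 loss lowered the set higher in RFP+ cells (127 of 172 genes negative, median log2 fold change -0.21, camera adjusted p = 1.0e-16, adjusted p = 0.020 with an estimated correlation). The opposite set rose slightly after Bcl6 loss (125 of 194 genes positive, median log2 fold change 0.10, camera adjusted p = 0.0027, adjusted p = 0.38 with an estimated correlation). That call was lost without Bcl6 littermate replicate 1 (adjusted p = 0.23) or knockout replicate 1 (adjusted p = 0.74). Tcf7 loss lowered the set higher in RFP+ cells (162 of 197 genes negative, median log2 fold change -0.21, camera adjusted p = 1.6e-29, adjusted p = 0.016 with an estimated correlation). It raised the opposite set (158 of 199 genes positive, median log2 fold change 0.13, camera adjusted p = 3.8e-24, adjusted p = 0.016 with an estimated correlation). In 99 of 170 genes of the first set measured in all 4 tables, the change followed the RFP+ direction in the Prdm1 knockout and opposed it in both others. The same held for 100 of 193 genes of the opposite set. The shares of each knockout given above would yield similar counts if signs were independent between knockouts. Both counts are therefore no evidence of reciprocity gene by gene. Immediate-early and heat-shock genes, higher in RFP+ cells, also fell in the Bcl6 knockout. With these genes left out before the sets were drawn, a later addition, every call of both sets in camera was kept.

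**Figure D3:**
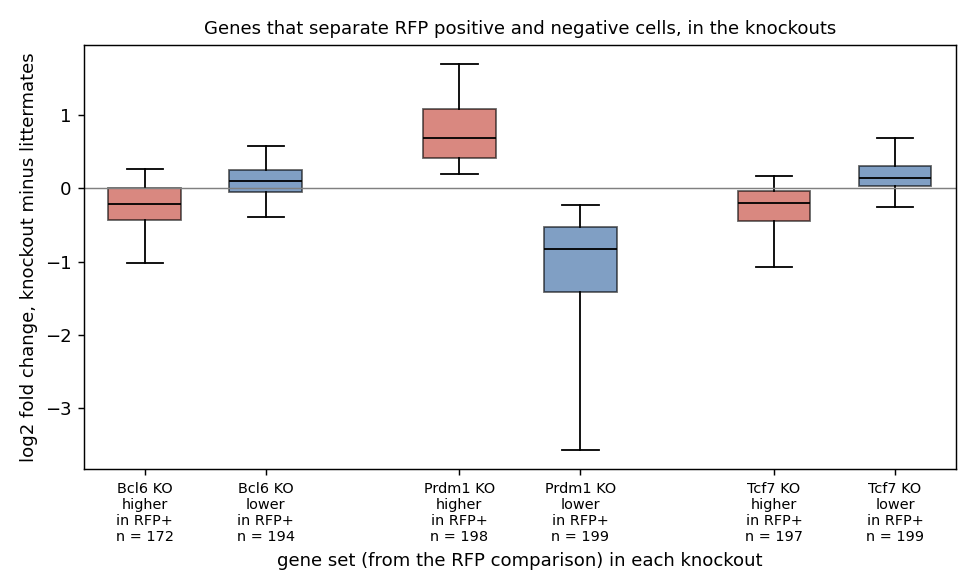
Log2 fold changes in each knockout of the up to 200 genes highest and lowest in RFP+ cells by smallest p (boxes span the quartiles, the line is the median, whiskers reach the 5th and 95th percentiles; the number of genes is written at each box). The medians of the set higher in RFP+ cells were -0.21 in the Bcl6, 0.68 in the Prdm1 and -0.21 in the Tcf7 knockout.

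Calls shared between comparisons were set beside the number that independent lists would share. Of genes higher in RFP+ cells, 149 were also higher in the Prdm1 knockout where independent lists would share 30.3. Of genes lower in RFP+ cells, 253 were also lower (57.1). In opposite directions there were 1, Lat (43 by chance), and 3, Dsp, Erbb3 and Krt18 (40.2), named after their values were seen. With the Tcf7 knockout, opposite directions prevailed. In it 107 genes higher in RFP+ cells were lower (26.2) and 119 lower ones were higher (35.1). The same direction was shared by 9 (26.5) and 23 (34.7). In the Bcl6 knockout, 24 genes higher in RFP+ cells were lower (5.32). Prdm1 and Tcf7 knockouts shared 64 genes higher in the Prdm1 and lower in the Tcf7 knockout (7.07) and 68 the other way (4.8). Bcl6 and Tcf7 knockouts shared 7 genes lower in both (0.519), Irak3 higher in both (0.0344) and 8 lower in the Bcl6 and higher in the Tcf7 knockout (0.584). Apart from Atf3, these 8 were transcripts of epithelial cells. The 7 lower in both were Ddit4, Ltb, Phlda1 and Slc2a6, with Dnajb1, Hspa1a and Hspa1b of the immediate-early and heat-shock list. Irak3, Atf3 and these 7 were named here after their values were seen.

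Across genes, fold changes of RFP+ cells went with those of the Prdm1 knockout (r = 0.72, rho = 0.67, exact permutation p = 0.0333, adjusted p = 0.20). They went against those of the Tcf7 knockout (r = -0.36, rho = -0.29, exact permutation p = 0.0667, adjusted p = 0.20) and the Bcl6 knockout (r = -0.25, rho = -0.21, exact permutation p = 0.133, adjusted p = 0.20). Between knockouts the correlation was negative for the Bcl6 and Prdm1 effects (r = -0.24, rho = -0.20, exact permutation p = 0.111, adjusted p = 0.20). It was also negative for those of Prdm1 and Tcf7 (r = -0.08, rho = -0.19, exact permutation p = 0.222, adjusted p = 0.22) and positive for those of Bcl6 and Tcf7 (r = 0.09, rho = 0.09, exact permutation p = 0.222, adjusted p = 0.22). None of the 6 passed after adjustment. The design cannot give a smaller p than 0.0333 with the RFP experiment or 0.111 between knockouts, and genes are not independent replicates.

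The Prdm1 effect minus the Bcl6 effect was tested gene by gene. A change in 1 knockout alone is enough for a difference, so this is no test of reciprocity. Gzma (-5.13, adjusted p = 3.9e-04, limma), Gzmb (-3.74, adjusted p = 9.2e-04) and Ccl5 (-2.41, adjusted p = 0.0010) had a negative difference on the log2 scale, lower after Prdm1 than after Bcl6 loss. Tcf7 (2.37, adjusted p = 0.0047), Id3 (3.45, adjusted p = 0.0016), Kit (1.77, adjusted p = 0.0055), Slamf6 (1.56, adjusted p = 0.011) and Ltb (2.05, adjusted p = 0.0025) had a positive one. Irak3 fell by 3.05 on the log2 scale in the Prdm1 knockout and rose by 1.94 in the Bcl6 knockout (difference -4.99, adjusted p = 0.0025). Id3, Ltb, Hspa1a and Hspa1b were called in both knockouts, lower after Bcl6 and higher after Prdm1 loss. The differences for Cd160 (1.49, adjusted p = 0.066) and Nr4a1 (1.69, adjusted p = 0.10) did not pass in this fit without a replicate term. They passed with a replicate block in each experiment (adjusted p = 0.033 and 0.010), where the counts below were 191 and 121. Of 9315 genes, 192 had a positive and 134 a negative difference. Of the same 9315, 9 were called in each of both knockouts, whether or not their difference passed. The pseudocount of 1 acts on FPKM in one experiment and on signal in the other, which shrinks the Bcl6 effects of weakly expressed genes more.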

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

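No test in this part was chosen only after its result was seen, but the reading of 1 of them, on the amount of epithelial RNA, was changed afterwards for the reason given there.

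The 2 libraries that the labels put in no group, which no comparison used, lay nearer to RFP+ than to RFP− cells in most genes that part these groups. Their Bcl6, Tcf7 and Cd160 values lay above the level of the RFP− libraries. Bcl6 was at 17.93 and 19.07 FPKM, against at most 3.59 in RFP− libraries. Tcf7 was at 260.7 and 271.5 FPKM, against at most 6.46. Cd160 was at 134.5 and 125.6 FPKM, against at most 69.8 in RFP− and at least 231 in RFP+ libraries. Prdm1 (0.728 and 0.66 FPKM), Gzma (91.2 and 81.8) and Gzmb (163 and 153) lay far below their RFP− levels. Cd8a (297 and 281) lay below both groups, with 542 to 612 in RFP+ and at least 871 in RFP− libraries. Of the 437 genes that differed at least 2-fold between RFP+ and RFP− cells, 412 lay nearer to the RFP+ mean in 1 of these samples and 413 in the other. Those genes were chosen because they part RFP+ from RFP− cells, so the counts cannot show that these samples were RFP+ cells. Of 9725 genes, 29 lay at least 2-fold above and 34 at least 2-fold below all 6 RFP libraries in both samples. Both are single samples without a group, so none of this was tested against a spread.

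Unlike all 6 RFP libraries, both samples held almost no transcripts of Paneth cells: Defa24 was listed at 0 in both (8.48 to 141 FPKM in the RFP libraries), Itln1 at 0 in both (1.92 to 22.1) and Lyz1 at 0.0791 and 0 (4.55 to 48.4), although the sort for T cells should remove epithelial cells from every library. A candidate explanation is epithelial RNA from another stretch of the gut than in the RFP libraries: of 20 further genes of small intestinal enterocytes, written down before their values were looked up, 15, a share of 0.75, lay below the lowest RFP library in both samples, where chance gives 3.57%. Less epithelial RNA of any kind stays open: 4 of 10 large intestinal genes, a share of 0.4, lay above the highest RFP library in both samples, which passes the bound of 1 in 4 that had been set against it. That bound was wrong, since it counted genes and not amounts, those 4 genes had a median of only 0.75 FPKM, and RNA of another stretch can be present while the total is lower. Outside those 10 genes, Car1 had the largest gap above the RFP libraries (8.11 and 7.43 FPKM, at most 0.0485). The erythroid genes Hba-a1 (17.4 and 18.4, at most 4.47) and Hbb-bs (18.8 and 17.7, at most 7.24) were higher too. These genes were picked after their values were seen, and the cells they came from were not tested. The labels of these samples are at odds: their tissue is given as small intestine, as for the RFP libraries, but their titles begin with LI where those of the RFP libraries begin with SI. Which of these holds was not settled, and no biological explanation was tested.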

How the results depend on the processing

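The edgeR fit and the fits that leave out epithelial, immediate-early or heat-shock genes were chosen after the results were seen; the test on other splits was not.

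No called gene named in the text changed direction under any alternative run for it, and all 78 alternative correlations kept their sign. Of the called genes among those named, 2 of 61 in the RFP comparison (Krt18 and Birc3), 6 of 13 in the Bcl6, 17 of 47 in the Prdm1 and 39 of 43 in the Tcf7 knockout lost their call in at least 1 alternative, in the Tcf7 knockout most often without the trend or in one fit over all experiments.

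The RFP counts (1591 higher, 2098 lower) were 3290 and 1173 with rescaled totals, 952 and 1393 in one fit over all experiments, which tested 3406 of the 3689 called genes and kept 2309, and 193 and 244 with a fold change of at least 2. Of its 12 lists, 2 held with an estimated correlation. The real split of the 6 libraries called 3689 genes and the highest of the other splits 0, so 1 of the 10 splits gave as many; they are too few for a share under 0.05.

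The Bcl6 counts (3 higher, 37 lower) were 87 and 104 in one fit. The lower count was 24 without a filter and 13 without immediate-early, heat-shock and epithelial genes, and the higher count 1 with the strict filter and 1 when centred. Leaving out 1 library gave 4 to 730 higher and 35 to 832 lower, both highest without knockout replicate 1; without knockout replicate 2 they were 68 and 131, and the higher count was 14 without littermate replicate 2. Of its 12 lists, 0 held with an estimated correlation and 1 in fry.

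The Prdm1 counts (471 higher, 279 lower) were 304 and 497 in one fit. The higher count was 210 with the strict filter, and the lower count 143 without the trend and 121 with a fold change of at least 2. Leaving out 1 library gave 342 to 721 higher and 227 to 534 lower, both highest without littermate replicate 2. EdgeR on recovered reads called 523 and 260, with 723 genes shared, and without epithelial genes limma called 415 and 272. With 10899 genes still tested, that last fit left out only the listed and the additional epithelial genes. It therefore sets no bound on the share of epithelial RNA. Of its 7 lists, 0 held with an estimated correlation and 0 in fry, both run without a term for sex.

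The Tcf7 counts (226 higher, 187 lower) were 6 and 3 without the trend, 4 and 25 in one fit, and 35 and 35 with a fold change of at least 2. Leaving out 1 library gave 123 to 399 higher and 120 to 357 lower, the lowest without knockout replicate 1 and the highest without littermate replicate 2 and replicate 1. Of its 8 lists, 0 held with an estimated correlation and 0 in fry. The fits without the trend and over all experiments pool the spread differently from the fit reported, and the cause of the lost calls was not tested.

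In the signature sets, 91 of 96 alternative tests kept their call. Lost were the Bcl6 set lower in RFP+ cells (adjusted p = 0.00272) with an estimated correlation (0.379) and, over the fits leaving out 1 library (2.91e-07 to 0.742), without knockout replicate 1 (0.742) or littermate replicate 1 (0.232), and both Prdm1 sets with an estimated correlation (0.0652 and 0.0513). The counts for the Prdm1 effect minus the Bcl6 effect (192 positive, 134 negative) were 567 positive without a filter and 72 and 85 with the strict filter. Leaving out 1 library gave 87 to 410 positive and 70 to 491 negative, both highest without Bcl6 knockout replicate 1; without Bcl6 littermate replicate 1 they were 90 and 70 and without replicate 2 87 and 74, and the negative count was 78 without Prdm1 littermate replicate 1 and 84 without Prdm1 knockout replicate 2. A group left with 1 library is assumed to vary like the others.

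The libraries share only a replicate number: same-numbered libraries deviated together with r of -0.23, -0.00 and -0.33 in the RFP, -0.46 in the Bcl6, 0.53 in the Prdm1 and 0.06 in the Tcf7 experiment. With the number as a replicate block, counts were 14 and 64 in the Bcl6, 1210 and 1176 in the Prdm1 (where it parts the sexes) and 495 and 482 in the Tcf7 knockout, and 1297 and 1695 in the RFP comparison. For other causes of moved counts than those named, the cause was not tested.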

Other observations

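The tests on other cell types and on dilution in the Prdm1 knockout, the test on handling, and both tests on the stretch of chromosome 16, were chosen only after the result was seen; the test on additional epithelial genes was not, though the value of 1 of them, Cbr1, had been seen.

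Several genes of Paneth cells moved in opposite directions in 2 knockouts of IELs, though no fixed list of such genes was tested. Defa24, Defa30 and Defa39 fell in the Bcl6 knockout (Defa39 3.78 ± 0.516 against 33.4 ± 3.29 FPKM), while Defa21, Defa22, Defa33, Lyz1 (3867 ± 240.3 against 2126 ± 163) and Itln1 (1689 ± 128 against 944 ± 2.13) rose in the Tcf7 knockout, where Reg3b fell (572 ± 3.8 against 1038 ± 63.9). In the Prdm1 knockout the log2 fold changes of Defa24, Defa30 and Defa39 were 1.81, 2.06 and 1.97. Without any knockout, Defa24 ran from 19.5 to 141 FPKM among the RFP− libraries. The erythroid genes Hbb-bs (264 ± 19.6 against 128 ± 19.8) and Hba-a1 (317 ± 29.97 against 167 ± 20.1) rose in the Tcf7 knockout as well. Both samples without a group had more S1pr1 (10.2 and 11.5 FPKM, at most 0.899 in the RFP libraries), Klf2 (121 and 125, at most 28.2) and Thy1 (60.2 and 59.0, at most 20.0) than all 6 RFP libraries, and less Itgad (6.93 and 6.37, at least 29.8) and Lag3 (32.2 and 28.8, at least 97.7), genes chosen after their values were seen. S1pr1 and Klf2 serve exit from tissues and Itgad encodes an integrin chain.

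Epithelial markers were higher in the Prdm1 knockout (25 of 41 called, 17 with quantile normalization, median log2 fold change 1.74, quartiles 1.43 and 1.99). A lower share of T cells would raise every other cell type alike. Medians were lower in the B and plasma cell list (0.36, upper quartile 0.52, 3 genes, none called, -0.19 with quantile normalization) and the myeloid list (0.42, upper quartile 1.16, 12 genes). The innate lymphoid and mast cell list of 4 genes overlapped (0.73, upper quartile 1.52). These small lists cannot decide it. The myeloid list holds Itgam (log2 fold change -3.49) and Fcgr3 (-1.17), which were also lower in RFP+ cells, beside H2-Aa (1.51). Dilution of T-cell RNA as the reason for the lower cytotoxic genes is argued against by the TCR signalling list, whose median was -0.04 beside -0.59 for the cytotoxic list without deleted genes. More epithelial RNA in the knockout libraries remains a candidate explanation: 29 additional epithelial genes outside the list had a median of 1.88, 19 of them higher, while the abundant listed genes Cdh1 (10124 ± 746 against 10497 ± 383), also on the residency list, and Epcam (2787 ± 34.3 against 2761 ± 23.4), which these IELs also express, did not pass. The sort for T cells should remove epithelial cells, and an effect of Prdm1 loss on the epithelium or on transcription in the T cells stays open, since the design confounds it with the libraries.

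In the Tcf7 knockout, 3 neighbouring non-coding gene models on chromosome 16 (93343716 to 93531385 on GRCm38) went from nearly no reads to a clear level: 1810053B23Rik from 0 and 0 to 141 and 140, 1700029J03Rik from 0 and 1.10 to 81.6 and 94.7, and Gm30695 from 0 and 0 to 88.6 and 97.5. Scattered changes that fall together by chance are argued against by random draws of 35 of the 15210 tested genes, of which 16 of 100000 held 3 consecutive genes (permutation test of which genes are called, p = 1.7e-04, counting the observed run). An effect on 1 stretch of the chromosome is a candidate explanation, since the larger log2 change of the tested neighbours Runx1 and Setd4 was 0.15 in size and the 16 tested genes within 1000000 bases had a median of -0.03. Tcf7 lies on chromosome 11. The loss of Tcf7 and the presence of Cd8cre, named only in the knockout genotypes, are both confounded with the change. Within this comparison they cannot be told apart. The Bcl6 and Prdm1 knockout genotypes also name Cd8cre, but the stretch was not looked up in those libraries. No other biological explanation was tested. These models were singled out after their values were seen.

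The mean log2 value of the immediate-early and heat-shock list was 6.87 in Bcl6 littermates and 5.99 in Bcl6 knockout libraries, while the widest range within any group was 0.416, in RFP− libraries. A test of handling as the source of this difference of 0.885 set it beside that range and left it undecided. The ranges within the Bcl6 groups were 0.0149 in littermates and 0.0782 in knockouts. RFP+ and RFP− libraries differed as well, with means of 7.00 and 6.09, and handling was not tested there. Bcl6 averaged below 1 FPKM in the Bcl6 littermates but at least 3.3 FPKM in every RFP library, 2 tables that were normalized apart. Bcl6 littermate replicate 2 listed 10 genes at 0, against 257 to 434 in the other libraries of that experiment. Sex could be read from Y-linked genes: the RFP and Bcl6 libraries all expressed them, the Tcf7 libraries did not, and the Prdm1 libraries held both.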
